A study of Mus musculus with 7 samples.

How the data were processed

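Bulk RNA-seq was measured in 7 mouse samples of long-term haematopoietic stem cells (LT-HSCs), the rare bone marrow cells that can rebuild all blood lineages. Per the labels, the cells were sorted as lineage-negative, Sca-1-positive, c-Kit-positive, CD150-positive and CD48-negative. The samples fall into 4 labelled as B4galt1 knockout (KO) and 3 labelled as wild type (WT). Groups and replicate numbers were taken from the labels. The labels do not say that the replicates are separate animals. Expression of Y-linked genes, given in the Results, differs between libraries within each group, so neither group came from a single animal. Whether every replicate is a separate animal is not known, so p-values measure only the spread between these samples, which may be partly technical. The library kit does not mark strand, per the labels' protocols, so reads from a gene and from an overlapping or antisense gene cannot be told apart by strand.

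The deposited files hold 1 row per transcript. Per the submitters' processing notes, the authors used cutadapt and Salmon 0.11.2 with mm10. The transcript set behind the quantification is not given in the sources used here. The values used are the estimated counts per transcript that the authors deposited, which need not be whole because Salmon divides reads among transcripts that share sequence. The deposited TPM values were used for the transcripts of B4galt1, and the deposited effective lengths for 1 alternative described as a length offset. Near-identical copies, such as pseudogenes, can exchange reads in this step. Sums over a pair are reported only for mt-Nd3 with Gm28438 and for the overlapping Gm45837 and Pde2a. Other genes that may share sequence, such as the pseudogene Gm12407, Hba-a1 and Hba-a2, are reported without such a check.

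Transcript identifiers were joined without their version to the GENCODE M21 annotation of GRCm38 (mm10). Of the 112092 transcripts per library, 111787 matched and 305 did not. The unmatched transcripts held between 0.084% and 0.123% of the estimated reads. Estimated counts were summed to 34932 genes, of which 21890 are protein-coding, and rounded to whole numbers. Totals ran from 23508985 to 34941390 estimated reads per library. Intervals and floors given for reads cover counting error only, since these are PCR-amplified reads without molecular identifiers.

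The groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter on low counts and Benjamini-Hochberg adjustment, at an adjusted p below 0.05. Log2 fold changes are KO minus WT. Standard errors (SE) were computed as the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts scaled to the TMM-adjusted library size and are given as mean ± SD. All adjusted p-values for genes come from this edgeR test unless another tool is named. On simulated counts for this comparison, with 14357 genes tested, the test recovered 38% of the 100 genes changed 2-fold and 82% of the 100 changed 4-fold, and it called 8 of the 14117 unchanged genes. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery below that level was not examined.

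Gene lists were fixed before the data were examined. They covered HSC identity, megakaryocyte and platelet, erythroid, granulocyte and monocyte, lymphoid, stromal and endothelial, Wnt targets and components, mucins, galactosyl- and sialyltransferases, N-glycan branching and fucosylation, galectins and lectin receptors, integrins and adhesion, cell cycle S and G2/M, interferon response, immediate early, unfolded protein response, JAK-STAT and thrombopoietin signalling, TGF-beta and BMP signalling, glycolysis and hypoxia, and sex-linked genes. A positional list held the genes within 10 Mb of B4galt1 on chromosome 4. Each list was tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists. The fry test was an alternative.

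The rule for named genes was also fixed before the data were examined. B4galt1 and Muc13 are always named. They are followed by the 10 higher and the 10 lower protein-coding genes of largest fold change among those that passed the test, had a mean log2 CPM of at least 1 and had group ranges that do not overlap. Up to 4 tested members of smallest p were then taken from each list. Some genes that the rule names are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

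The alternatives were RLE and upper quartile scaling, no filter and a stricter filter on low counts (at least 1 CPM in 3 libraries and 50 reads in total), DESeq2 1.42.0, limma voom with quality weights, an offset for average transcript length, the replicate number as a block, sex as a covariate, protein-coding genes only, and each library left out in turn. After seeing the data, KO replicate 4 and WT replicate 2 were left out together, and the 5 libraries with over 100 CPM in the sum of 4 Y-linked genes were compared alone. Sequences of mitochondrial genes and their nuclear copies were aligned with Biopython from the annotation's transcripts. The transcripts that did not match the annotation were left out of every test.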

Results

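RNA-seq libraries of LT-HSCs sorted from the bone marrow of mice on a 129S1 and C57Bl/6 background were compared between 4 libraries labelled B4galt1 KO and 3 labelled WT. B4galt1 encodes a galactosyltransferase that adds galactose to the antennae of N-glycans. The totals were 24724079, 27148889, 26158418 and 34941390 estimated reads in KO replicates 1 to 4, and 30325691, 23508985 and 23674617 in WT replicates 1 to 3. Multidimensional scaling placed all libraries labelled KO on 1 side of the first dimension, which held 38.6% of the variance, and all WT libraries on the other.

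The targeted gene came first, as a check on the labels. B4galt1 (ENSMUSG00000028413, GRCm38 chromosome 4, 40804602 to 40854005, minus strand) was not lower in the libraries labelled KO beyond the spread between replicates. Its level was 15.9 ± 2.28 CPM (SD, n = 4) in these and 18.3 ± 6.62 CPM (SD, n = 3) in WT. By library it was 19.3, 14.9, 14.8 and 14.6 CPM in KO replicates 1 to 4, and 19.2, 24.4 and 11.3 CPM in WT replicates 1 to 3. The log2 fold change was -0.20 (SE 0.27, edgeR adjusted p = 0.758), with a 95% interval from -0.89 to 0.49, and the sign turned to 0.04 without WT replicate 2. The counts cover the whole gene, so they do not show whether part of the transcript is missing. The annotated transcript of 3983 nt carried 495, 404, 393.5 and 405.5 estimated reads in the KO replicates and 564, 521 and 254.2 in the WT replicates. The 1413 nt transcript carried 133.5 estimated reads in KO replicate 4 and at most 11.5 in any other library. Because the RNA level does not separate the groups, each direction below rests on the labels alone.

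Muc13 (ENSMUSG00000022824, chromosome 16, 33794037 to 33819934, plus strand), a transmembrane mucin, had 434.7 ± 131 CPM (SD, n = 4) in the libraries labelled KO and 239.5 ± 28.2 CPM (SD, n = 3) in WT. All 4 of the former lay above all 3 of the latter. The log2 fold change of 0.86 (SE 0.232) did not pass the test (edgeR adjusted p = 0.0998), and its 95% interval ran from 0.26 to 1.46. It passed with DESeq2 (0.84, adjusted p = 0.00971), with limma voom (0.70, adjusted p = 0.0289), with sex as a covariate (0.87, adjusted p = 0.0197) and without KO replicate 1 (0.99, adjusted p = 0.0437). Over all alternatives the adjusted p of Muc13 ran from 0.00971 to 0.293.

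Members of the megakaryocyte and platelet list made up 31 of the 244 genes that fell and 4 of the 10 lower genes named by size of change. Lower genes outside the list were not screened for this lineage. Ppbp, a platelet chemokine, was at 17.02 ± 3.26 CPM in the libraries labelled KO and 2460 ± 1060 CPM in WT. Myl9, a myosin light chain, was at 0.677 ± 0.573 against 416.6 ± 61.6 CPM, and Gp6, the platelet collagen receptor, at 0.308 ± 0.162 against 50.4 ± 13.5 CPM. Across the transcriptome 88 genes were higher and 244 lower in the libraries labelled KO, out of 14695 tested. All 332 had groups that did not overlap, which 15.7% of all tested genes showed and chance gives in 5.7%. Changes over 4-fold numbered 30 higher and 126 lower.

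**Figure D1:**
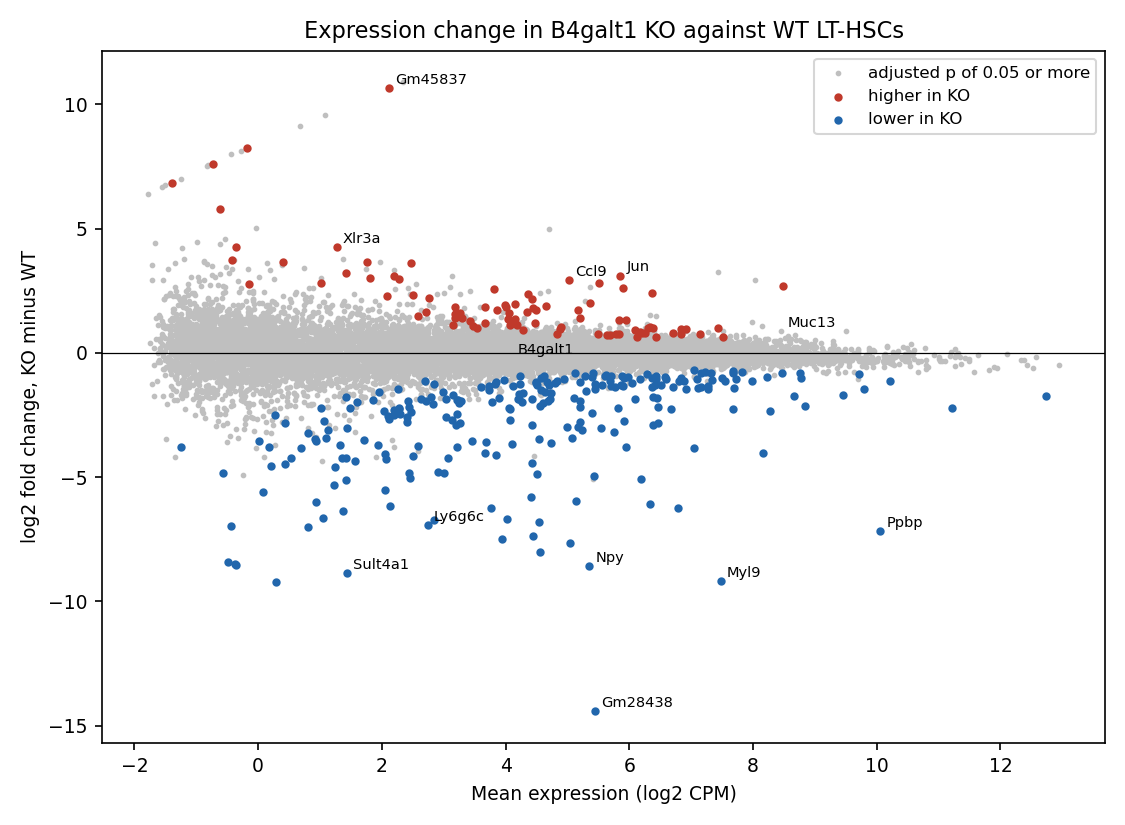
Log2 fold change (KO minus WT) against mean expression in log2 CPM for the 14695 genes tested, 1 point per gene, with the 88 higher genes in red and the 244 lower genes in blue. The labelled genes include Ppbp at -7.18 and Jun at 3.11. Fitted values for genes with no reads in 1 group, such as Gm45837 and Gm28438, depend on the prior count and are not fold changes.

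The 10 lower genes named by the rule were Myl9 (log2 fold change -9.18), Sult4a1, Npy (-8.59), Mpig6b (-8.03), Cald1 (-7.65), Slc6a4 (-7.49), Gp6 (-7.36), Ppbp (-7.18), Ly6g6c (-6.94) and Tesc (-6.79). Sult4a1 had 1 read in the libraries labelled KO and 455 in WT, a ratio of 720 with a counting interval from 129 to 28500. With 1 library left out some of these values moved by over 1.5 times, to -9.96 for Myl9 (without KO replicate 4), -9.25 for Npy and -9.60 for Mpig6b (KO replicate 1), and -8.70 for Cald1 and -9.86 for Slc6a4 (KO replicate 3). With the length offset Gp6 was at -8.11 and Tesc at -5.63. Mpig6b and Ly6g6c overlap on opposite strands of chromosome 17, so the division of reads between them is uncertain. Npy is neuropeptide Y, and Slc6a4 is the serotonin transporter. The 10 higher genes were Gm45837, Xlr3a (4.27), Atp8b4 (3.64), Il6 (3.62), Gpr34 (3.21), Jun (3.11), Hdc (3.11), Sparc (2.99), Cyp4f18 (2.96) and Ccl9 (2.92). Without WT replicate 1, Atp8b4 was at 5.27 and Hdc at 4.15, and without KO replicate 3 Gpr34 was at 2.61 (adjusted p = 0.0723). With the length offset Xlr3a was at 5.70, and Atp8b4 lost its call at 2.85 (adjusted p = 0.157). Il6 encodes the cytokine interleukin 6, and Hdc the enzyme that makes histamine. Jun ranged from 29.5 to 200.8 CPM among the libraries labelled KO and from 9.48 to 11.9 CPM in WT, and was at 2.41 without KO replicate 4. Gm45837 had 0 reads in WT and was at least 179-fold higher in the libraries labelled KO against a floor of 3 counts over the group. It overlaps Pde2a on chromosome 7, which was at 0.939 ± 0.414 CPM against 12.7 ± 4.73 CPM, and the division of reads between these genes is uncertain. The sum of both was 8.3 ± 1.2 CPM in the libraries labelled KO and 12.7 ± 4.7 CPM in WT and overlapped between the groups. Pde2a was chosen after its values were seen.

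In the megakaryocyte and platelet list, 31 of 51 tested members fell and 0 rose, or 38 lower when adjusted over the list alone. The median log2 fold change was -1.35 (camera adjusted p = 8.6e-33), and the call held with an estimated correlation (adjusted p = 0.00707). Among members chosen after their values were seen, Pf4 fell by 2.23 and Vwf by 1.76 on the log2 scale, with Pf4 still at 915.4 ± 428 CPM. F13a1, a clotting factor subunit, fell by 6.24. The transcription factors of the lineage did not pass: Gata1 was at 0.40, Gfi1b at 0.06, Nfe2 at -0.04, Zfpm1 at -0.21 and Fli1 at -0.48. Their median was -0.04, against -1.54 for the 46 other members, and this subset was chosen after its values were seen. Tmsb4x, an abundant actin-binding transcript, was also lower (-1.75) and was chosen after its value was seen, and mitochondrial genes took 2.53% to 3.15% of reads in the libraries labelled KO and 3.25% to 4.75% in WT.

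**Figure D2:**
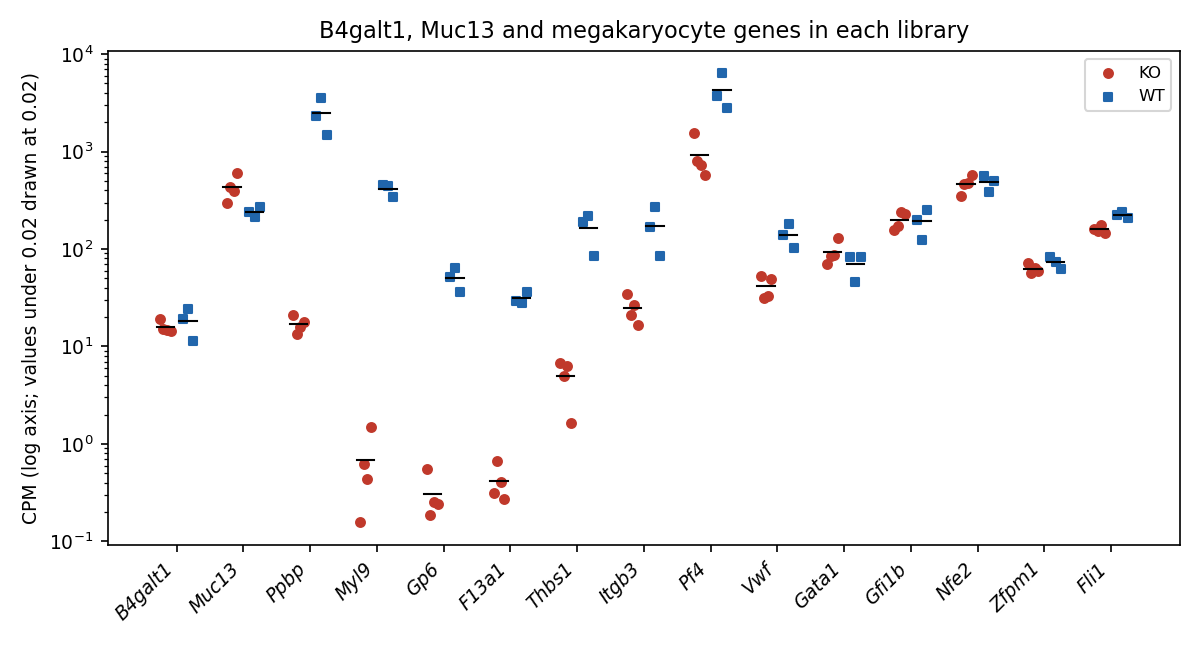
CPM on a log axis for B4galt1, Muc13 and genes of the megakaryocyte list in each library (circles, 4 libraries labelled KO; squares, 3 WT libraries; bars, group means). Ppbp lies between 13.5 and 21.1 CPM in the libraries labelled KO and between 1468 and 3579 CPM in WT, while Nfe2 overlaps between the groups.

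In the HSC identity list, 4 of 34 members fell and 0 rose, with 8 lower when adjusted over the list alone. They include Sult1a1 (-2.03), Cdkn1c and Mllt3 (-1.15). Cdkn1c, a cell cycle inhibitor, was at 8.45 ± 3.02 against 33.7 ± 5.47 CPM. The list passed with the preset correlation (median -0.37, camera adjusted p = 9.4e-06), and the call was lost at adjusted p = 0.0851 with an estimated correlation. Integrins and adhesion genes had 4 lower and 0 higher of 31, or 5 lower and 3 higher adjusted over the list alone, with Itgb5 (-4.84, and -5.70 with the length offset), Itgb3 (-2.81), Itga6 (-1.11) and Jam3 (-1.10). Of these, 1, Itgb3, is also counted in the megakaryocyte and platelet list. Their camera adjusted p was 0.00958, and adjusted p = 0.167 with an estimated correlation. Wnt targets and components had 1 higher, Jun, and 1 lower, Ccnd1 (-1.64, and -0.98 with adjusted p = 0.22 with the length offset), of 45, or 1 higher and 2 lower adjusted over the list alone. Their camera adjusted p was 0.0122, direction down, and adjusted p = 0.256 with an estimated correlation.

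Other lists passed camera upward with the preset correlation. In the lymphoid list 1 of 20 members rose, Satb1 (1.65), or 4 adjusted over the list alone (camera adjusted p = 0.00958; adjusted p = 0.107 with an estimated correlation). Galectins and lectin receptors had 0 of 15 called by edgeR (5 higher at an unadjusted p below 0.05, 1 higher with DESeq2 and 3 with limma voom), or 2 higher adjusted over the list alone (camera adjusted p = 0.00958; adjusted p = 0.107 with an estimated correlation), with Lgals3 at 1.96, which did not pass the test. Of 53 cell cycle S and G2/M genes, Cenpe (1.02) and Cenpf (0.80) rose, and also 2 adjusted over the list alone (camera adjusted p = 0.0118; adjusted p = 0.691 with an estimated correlation). Of 50 interferon response genes, Oas2 (2.21) rose, and 1 adjusted over the list alone (camera adjusted p = 0.0469; adjusted p = 0.691 with an estimated correlation). Of 27 immediate early genes, Jun rose, and 3 adjusted over the list alone (camera adjusted p = 0.0122; adjusted p = 0.691 with an estimated correlation). Fos, at 4.98, did not pass (edgeR adjusted p = 0.0772). It was at 10.9, 1.96, 26.4 and 138.1 CPM in KO replicates 1 to 4 and its value was 3.22 without replicate 4. It passed with DESeq2 (adjusted p = 0.00272), no filter (0.026), sex as a covariate (0.0199) and without KO replicate 2 (0.0228), and its adjusted p reached 0.318 over the alternatives. The fry test, which asks whether a list's genes move 1 way and does not compare them with other genes, passed for the megakaryocyte and platelet list (adjusted p = 5.09e-05) and for HSC identity, lymphoid, galectin and integrin genes (adjusted p = 0.0124 each). It did not pass for Wnt (adjusted p = 0.106), cell cycle and interferon (0.309 each) or immediate early genes (0.343).

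Markers of other blood and marrow cells moved in both directions. Of 25 granulocyte and monocyte genes, Ms4a3 (1.70) rose while F13a1, also counted in the megakaryocyte and platelet list, and S100a9 (-2.23) fell, with 7 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.648). Of 27 erythroid genes, Sptb (-2.54) fell, with 2 lower adjusted over the list alone (median 0.35, camera adjusted p = 0.665). Of the members, 18 lay above 0 and 9 below, and Hba-a1 was at 2.90 ± 5.20 against 94.9 ± 42.9 CPM without passing (adjusted p = 0.0622). Without KO replicate 1, Hba-a1 was at -8.38 (adjusted p = 0.00033), and its adjusted p passed under other alternatives too. Of 10 stromal and endothelial genes, Sparc rose, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.766), and the list's median (-0.17) and mean (0.02) differ in sign.

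The lists of glycosylation genes did not pass camera, and edgeR called 0 of their members. Of 35 galactosyl- and sialyltransferases, 1 was higher and 2 lower at an unadjusted p below 0.05, DESeq2 and limma voom each called 1 lower, and edgeR called 0 adjusted over the list alone (median 0.09, camera adjusted p = 0.901). C1galt1, which builds the core of O-glycans, was at -1.01 (adjusted p = 0.0148 with DESeq2) and St3gal1 at -0.59. Of 32 genes of N-glycan branching and fucosylation, edgeR called 0, with 5 higher and 2 lower at an unadjusted p below 0.05, DESeq2 called 2 higher and limma voom 1 higher, and edgeR 1 higher adjusted over the list alone (camera adjusted p = 0.901), with Fut8, the core fucosyltransferase, at 1.25 (edgeR adjusted p = 0.0543, DESeq2 adjusted p = 0.000617). This list's median (-0.02) and mean (0.08) differ in sign. Of 9 mucins, edgeR called 0, with 3 higher at an unadjusted p below 0.05, DESeq2 called 3 higher and limma voom 2 higher, and edgeR 3 higher adjusted over the list alone (camera adjusted p = 0.266), with Cd34 at 1.09.

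The remaining lists did not pass camera. Of 36 unfolded protein response genes Edem1 (-0.95) fell, with 3 lower adjusted over the list alone (adjusted p = 0.18). Of 30 JAK-STAT and thrombopoietin signalling genes Csf2rb (1.80) rose and Sh2b3 (-1.03) fell, with 3 higher and 2 lower adjusted over the list alone (adjusted p = 0.648). Of 31 TGF-beta and BMP signalling genes Thbs1 (-5.07), Ltbp1 (-4.05) and Cdkn1c fell, 2 of which are also in the megakaryocyte and platelet list. Adjusted over the list alone, 3 were higher and 3 lower (camera adjusted p = 0.282 for the list). Ltbp1 was at -2.35 with the length offset and ran from -4.66 to -3.75 with 1 library left out. Of 31 glycolysis and hypoxia genes edgeR called 0, with 1 higher and 2 lower at an unadjusted p below 0.05, DESeq2 and limma voom each called 1 lower, Slc2a3, and edgeR 0 adjusted over the list alone (adjusted p = 0.692), and the list's median (0.03) and mean (-0.01) differ in sign. Of 139 genes within 10 Mb of B4galt1, 5 fell, with 3 higher and 6 lower adjusted over the list alone (adjusted p = 0.692): Tpm2 (-3.17), Fam214b (-2.57), Ccl27a (-3.80, and -4.46 without KO replicate 3), Gm12407 (-4.82, and -5.64 without KO replicate 2) and Il11ra1 (-1.03), the last chosen after its value was seen. Of the 4 sex-linked genes edgeR, DESeq2 and limma voom called 0, and edgeR also 0 at an unadjusted p below 0.05 and 0 adjusted over the list alone (adjusted p = 0.648).

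**Figure D3:**
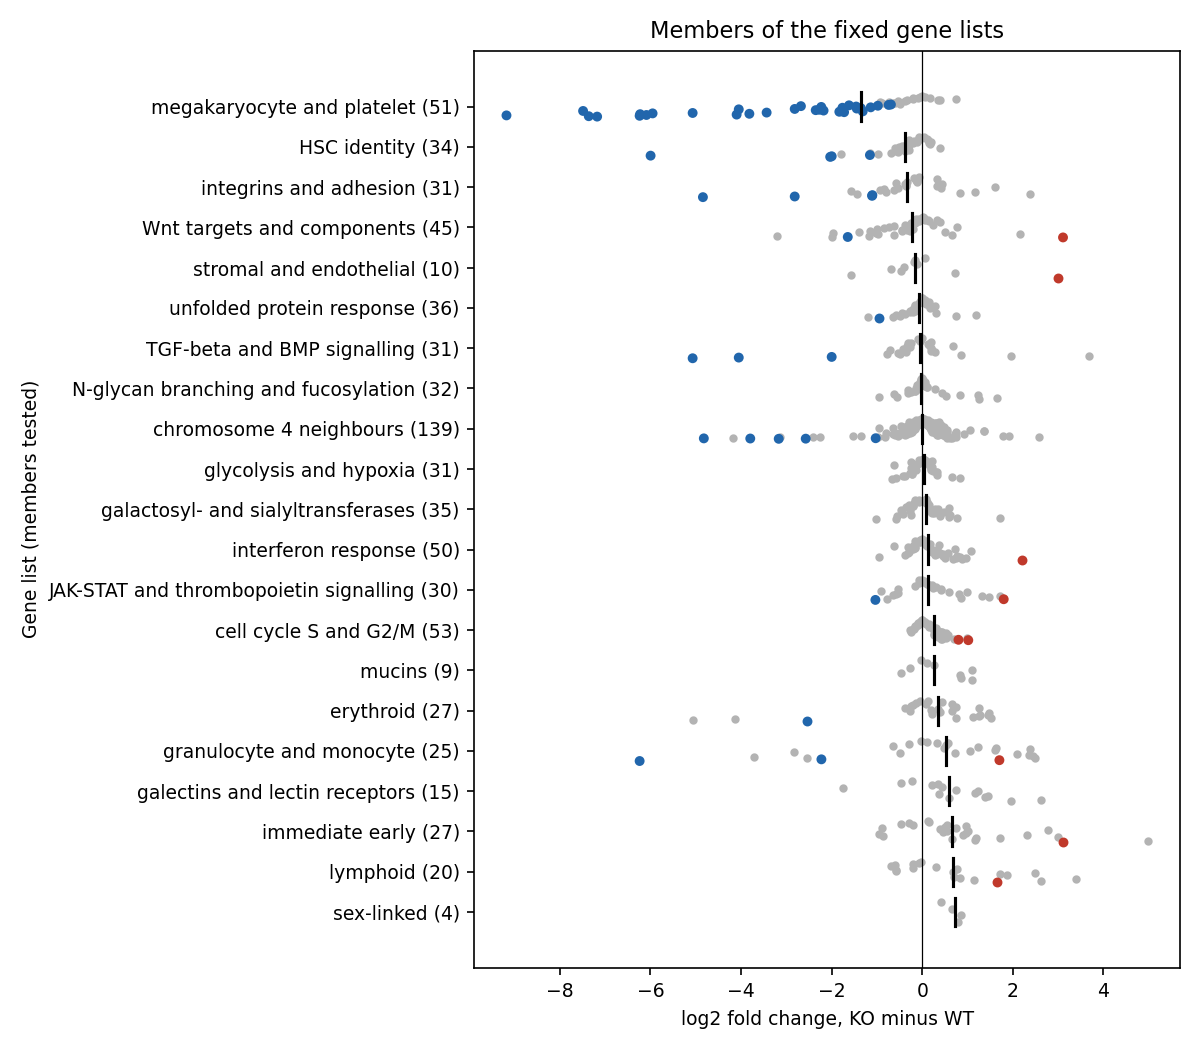
Log2 fold change (KO minus WT) of each tested member of the fixed gene lists, 1 point per gene, red for higher and blue for lower at an adjusted p below 0.05, grey otherwise, with the median as a black bar and the members tested in brackets. The megakaryocyte and platelet list lies farthest to the left, with a median of -1.35.

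The sum of 4 Y-linked genes was 330.2, 354.1, 364.6 and 10.9 CPM in KO replicates 1 to 4 and 266.5, 255.7 and 6.0 CPM in WT replicates 1 to 3, so each group held 1 library without male-pattern expression. Among the 5 libraries with it, 92 genes were higher and 256 lower. The other 2 libraries, 1 per group, allow no comparison of their own. Without KO replicates 2 and 3 in turn, the count of higher genes fell to 38 and 30 and of lower genes to 157 and 167. Without WT replicates 1, 2 and 3 in turn, the counts were 39, 37 and 45 higher and 174, 180 and 189 lower. They were 64 higher and 228 lower without KO replicate 1, and 130 and 279 without KO replicate 4. Of the 46 named genes that passed, 19 lost the call without at least 1 of the 7 libraries: Atp8b4, Gpr34, Jun, Hdc, Sparc, Cyp4f18, Mllt3, Sptb, Ms4a3, S100a9, Satb1, Ccnd1, Itga6, Jam3, Cenpf, Edem1, Sh2b3, Csf2rb and Gm12407. The length offset called 214 higher and 252 lower genes, a share of 45.9% higher against 26.5%.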

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

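Every test in this part was chosen after the result was seen. Of 100 quantities examined in the 4 libraries labelled KO, 16 had 1 library far from the other 3. Chance gives about 1 in 20 for independent, normally spread values, which these are not, so the shares cannot be set side by side. The 16 include 4 Y-linked genes, low in the library without male-pattern expression, and Sult4a1, which had 1 read over the group. Groups of 3 were not examined.

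In replicate 4 the Y-linked genes stood low: Kdm5d at 8.94 CPM against 37.1 to 40.6, Uty at 1.86 against 43.4 to 49.9, Ddx3y at 0.054 against 105.8 to 121.5 and Eif2s3y at 0.0811 against 140.4 to 160.4. Sfrp1 was at 0.648 CPM in replicate 4 against 1.91 to 2.16, and Edem1 at 37.3 against 24.2 to 25.5. In replicate 3, Gpr34 was at 8.41 CPM against 2.50 to 2.92, Irf7 at 32.3 against 19.4 to 20.3, Cald1 at 0.987 against 0.135 to 0.234, Slc6a4 at 0.695 against at most 0.111, and Sult4a1 at 0.0366 against 0. In replicate 1, Mpig6b was at 0.664 CPM against 0.027 to 0.111, Hba-a1 at 10.7 against at most 0.695 and Hba-a2 at 10.6 against at most 0.366. Hk2 was at 14.1 CPM in replicate 2 against 17.1 to 17.4.

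B4galt1 was at 19.3 CPM in KO replicate 1 against 14.6 to 14.9 in the other 3, and its RNA was not lower in this group. A single mislabelled library goes against the correlations, since each of the 7 libraries correlated better with its own group than with the other, by at least 0.00989 in mean r. This check cannot see labels exchanged between the whole groups, or groups that share the same B4galt1 genotype. A disrupted allele that is still transcribed may leave such a level, which the ratio of 0.87 between the groups cannot tell apart from an intact gene without counts per exon. Whether the gene product is missing was not measured here.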

How the results depend on the processing

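Leaving out KO replicate 4 with WT replicate 2, and comparing only male-pattern libraries, were chosen after seeing the data. No called gene changed sign under any alternative. Counts of higher and lower genes (88 and 244) became 352 and 514 with DESeq2 (40.6% higher), 269 and 439 with limma voom (38% higher), 214 and 252 with the length offset, and 218 and 396 with sex as a covariate. They were 137 and 310 without KO replicate 4 and WT replicate 2, and ran from 30 to 130 and from 157 to 279 with 1 library left out. The replicate block gave 58 and 182 and kept 207 of the 332 calls. Deviations from the group mean correlated at -0.053, -0.12 and -0.039 between samples of the same number. Between samples of different numbers they ran from -0.251 to 0.248. With so few libraries per group, this check cannot show whether samples of the same number share a source or batch. Muc13 passed with DESeq2 (0.84), limma voom (0.70) and sex as a covariate (0.87), and ran from 0.66 to 0.99 with 1 library left out. B4galt1 ran from -0.467 to 0.037 and reached 0.081 without KO replicate 4 and WT replicate 2. Over the named genes and all alternatives, 1577 results kept their side of the threshold, 97 lost it and 125 gained it, and for the lists 372, 40 and 8 did. Only uncalled results turned direction, and for lists this is the direction of the set test, which can turn while the median keeps its sign. Where it turned, medians with DESeq2 were 0.50 (granulocyte and monocyte), -0.19 (stromal and endothelial) and -0.032 (N-glycan), with voom 0.13 (erythroid), and with the replicate block -0.059 (galactosyl- and sialyltransferases). The N-glycan test also turned at medians of -0.025 with the stricter filter, -0.006 with the length offset and -0.011 with sex as a covariate. Fry, which keeps the medians, gave the other direction for N-glycan (-0.018) and granulocyte and monocyte genes (0.52). In male-pattern libraries the camera direction turned for stromal genes at -0.049 and for galactosyltransferases at -0.11, whose median changed sign here and with the block. With 1 library left out, medians ran from -0.21 to 0.57 (erythroid), -0.101 to 0.073 (glycolysis), -0.425 to -0.052 (stromal), -0.063 to 0.014 (N-glycan), -0.055 to 0.124 (galactosyltransferases) and 0.18 to 1.10 (sex-linked), and Eif2s3y from -0.18 to 0.96. The cause was not tested. At this depth and spread, 38% of simulated 2-fold changes were recovered among genes with a mean of at least 1 CPM.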

Other observations

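Apart from the splits of the libraries, the tests in this part were chosen after the result was seen. Cd48, whose product the sort selected against, was at 125.7 ± 15.2 CPM in the libraries labelled KO and 23.9 ± 9.24 CPM in WT (log2 fold change 2.40, adjusted p = 0.000804), and Plac8 at 558.4 ± 70.6 against 87.1 ± 16.4 CPM (2.68). Fcer1a, a subunit of the mast cell and basophil IgE receptor, was at 72.0 ± 36.9 against 10.2 ± 8.52 CPM. The other subunits did not pass: Fcer1g was at -0.97 (edgeR adjusted p = 0.222) and Ms4a2 at 3.10 (edgeR adjusted p = 0.242). Tyrobp, a myeloid adaptor, was at 36.5 ± 12.4 against 9.77 ± 3.32 CPM. Slamf1, which encodes the CD150 of the sort, was at 95.2 ± 19.2 against 107.5 ± 30.6 CPM. These genes were named after their values were seen.

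Each of 3 gene lists was written from such calls, so it was tested only on members whose values had not been seen when it was written. This leaves out every called member and weakens the tests. None passed after adjustment over the 3 lists. Contraction genes outside the megakaryocyte list had a median of -0.28 over 31 members, with 24 below 0 (camera with an estimated correlation, p = 0.0313, adjusted p = 0.094). Mast cell and basophil genes had a median of 0.26 over 22 members (adjusted p = 0.208), and genes of CD48-positive multipotent progenitors 0.53 over 18 members, with 15 above 0 (adjusted p = 0.147). These hypotheses stay open. Over the whole lists, called members included, p was 0.00038, 0.0672 and 0.0289, which is circular and no evidence.

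Of the 35 splits of the 7 libraries into 4 and 3, 1 gave as many higher genes and 1 as many lower genes, in each case the real one. The real split called 88 and 244, and the highest other split called 1 in each direction. No other grouping of these 7 libraries gave such counts, and 1 of 35 is the smallest share this test can give. It does not address differences between sorts or batches that run along the labels.

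The fall of megakaryocyte and platelet genes in the libraries labelled KO is the first pattern weighed. Of the 31 called members, 9 lay under 5% of the WT level in these libraries. The other called members ran up to 61.93% of the WT level, for Lat. Lower depth goes against the totals, whose medians stood at a ratio of 1.12, KO to WT. Erythroid carry-over together with platelets stays open. Of 4 adult globin genes, 2 were lower by more than 2 SE, Hba-a1 (-5.06) and Hba-a2 (-4.14), though neither passed the edgeR test. These 2 genes may share sequence and exchange reads, so they may not count as separate observations. With 1 library left out, Hba-a1 ran from -8.38 to -4.61 and Hba-a2 from -8.45 to -3.70. Hbb-bs (-0.24) and Hbb-bt (1.51) were not lower by more than 2 SE. In the erythroid list, 18 of 27 members lay above 0 (median 0.35) and 9 below. Platelet RNA carried into the WT sorts may account for the pattern and cannot be told apart from a difference between genotypes. The WT level above the KO mean, as a ratio of WT 2 to WT 3, had quartiles 2.05-fold apart over the 31 called members. These quartiles were 2.1-fold apart over the 9 members under 5% of the WT level, and 2.12-fold over 213 other lower genes. Those other genes were not screened for platelet genes outside the list, so the comparison cannot decide. A difference of genotype or of strain background also stays open, untested.

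Reads on mt-Nd3 and its nuclear copy Gm28438 (mitochondrial sequence on chromosome 1) split by group. Gm28438 took 0 reads in each library labelled KO, which allows at most 0.0885% of the pair's reads, and 54.8%, 54.4% and 61.2% in WT replicates 1 to 3. Random assignment between identical copies goes against the gap of 54.4 percentage points between the groups. A mitochondrial sequence difference between the groups that moves reads between near-identical copies may account for this: the copies differ at 1 of 345 aligned positions, and the sum of both overlapped between the groups (131.2 ± 30.2 against 180.3 ± 60.9 CPM). Sequence reads were not used here, so no variant was seen.

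Within 5 Mb of B4galt1, 5 of 82 tested genes were called, all lower (6.1% against 2.24% elsewhere, Fisher's exact test, two-sided, p = 0.038), while p was 0.247 within 10 Mb and 0.331 within 20 Mb. These 3 distances were not adjusted for one another. Fisher's exact test also counts called genes as independent, which close neighbours may not be. Ccl27a (41769467 to 41774247) and the pseudogene Gm12407 (41791989 to 41793601) lie close together.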
